A study of Mus musculus with 3 samples.

How the data were processed

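Gene expression was measured in the livers of 3 mice, 2 given the control virus and 1 the Cre virus, with 1 single-colour oligonucleotide array per mouse. RNA was extracted with Trizol and labelled with biotin by in vitro transcription with a 3-prime expression kit, per the labels' protocols. The deposited values are log2 expression per probe set, made with Partek 6.5 and RMA, per the submitters' processing notes; RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set. The log base was not given in the sources used here; base 2 was taken from the range of the values, which reach 15.048 on each array, and every fold rests on it. Values are not centred per gene, and higher values mean more signal. Equalised distributions hide a shift shared by all genes, and RMA compresses differences near the array background, where no detection calls were used. The labels call the control mice biological replicates. They also call the control livers wild type and the Cre liver an HNF4alpha knockout, whereas the series design describes floxed mice for both viruses. This conflict was not resolved: if the controls were not floxed, each difference between Cre and control also holds that of genotype. The sex of the mice is not given in the sources used here.

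Of the 45101 probe sets, 64 were array controls. Of the others, 34945 listed 1 gene in the platform annotation, 932 several and 9160 none; probe sets with several genes or none were not named. Symbols were updated by Entrez ID for 34741 probe sets through a mouse gene table of the GRCm38.p6 assembly, used for names only, since no genome was used here and probe positions were not analysed. The brightest single-gene probe set by mean stood for each of 18193 genes, and those whose mean lay at or above the 30th percentile (3.77) were fitted, 12735 in all. That mean included the Cre array, so a gene dim in the controls could enter through a high Cre value. Of 155 genes named by rule, 58 had several probe sets, and in 13 these differed in sign.

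Arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), Cre virus against control virus. The controls left 1 residual degree of freedom per gene, and moderation added 3.18 prior degrees of freedom. The lone Cre array was assumed to vary like the controls. Adjusted p values are Benjamini-Hochberg values over all fitted genes, two-sided, with a threshold of 0.05. A second rule without a test counted genes at least 1 log2 unit above or below both controls. For Hnf4a each probe set was tested over all probe sets past the same filter.

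Before the data were examined, 36 gene lists were fixed, covering hepatocyte functions, responses, sample quality, other cell types and sex. Those with at least 5 fitted members, 34, were tested with camera in limma with an inter-gene correlation of 0.01, adjusted over the lists. Of these, 11 passed as lower and 5 as higher. With the correlation estimated from the data, which leaves 1 degree of freedom for each list's test, 0 passed. Those estimates rest on the control arrays alone. They were 0.778 for fatty acid oxidation and PPARalpha targets and 0.714 for cholesterol synthesis and uptake, but -0.0769 for complement. Where list members vary together that strongly, the preset 0.01 makes the adjusted p too small. Each list's genes were also adjusted over the list alone. Named genes were Hnf4a, the 10 largest rises and 10 largest falls past the threshold outside both controls, and up to 4 members of each list with the largest absolute change; any member could be named to describe its list, and clones and predicted genes were not named.

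The fit was tested on simulated data for the comparison of Cre with control virus, with 12735 genes and 50 changed genes per size in each of 20 runs. It recovered 7.6% of genes changed by 1 log2 unit, 82.6% at 2, 95.9% at 3 and 98.6% at 4, and 5.67% of its calls were false. A list shifted by 1 log2 unit was found in 100% of runs, and unshifted lists had p under 0.05 in 4.7%. The simulated genes varied independently of each other, and the simulated Cre array had the spread of the controls. These rates therefore do not cover genes regulated together or a Cre liver that varies more than the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

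Alternatives set before the data were examined were eBayes without trend or with robust moderation, no filter or a filter at the 50th percentile, median centring, quantile normalization, the mean of a gene's probe sets, every probe set alone, no probe sets with the suffixes _s_at, _x_at or _a_at (called shared or mixed here, as they can read more than 1 transcript), each control left out, other thresholds, an estimated correlation and a rank-based list test. The share of calls that were higher was 56.3%, 61.0% after median centring and 54.2% after quantile normalization, and the median of all fitted genes was 0.09, 0.10 and 0.02.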

Results

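Total liver RNA from 3-month-old mice on a mixed background was profiled 1 week after a single intraperitoneal injection of 400 microL of virus. HNF4alpha, the product of Hnf4a, is a nuclear receptor that drives many hepatocyte genes. Both viruses were adeno-associated viruses of serotype 8, and carried either EGFP (control virus, n = 2 mice) or the iCre recombinase (Cre virus, n = 1 mouse), which removes floxed DNA. The sample titles name them MUP-EGFP-AAV8 and MUP-iCre-AAV8. The sources differ on genotype: the series design describes floxed Hnf4a mice for both viruses, whereas the sample labels call the control livers wild type and the Cre liver an HNF4alpha knockout, so a difference in genotype between the groups before injection is not ruled out. Each mouse gave 1 array with 45101 probe sets, and the median log2 expression per array was 4.18, 4.15 and 4.16. Across probe sets, which are not independent replicates, Pearson's r was 0.993 between the control arrays, and 0.970 and 0.972 between the Cre array and each control. The number of arrays limits the precision, and the Cre value of every gene rests on 1 mouse. Differences below are Cre minus the control mean on the log2 scale, with limma's moderated standard error (SE), and a gene rose or fell where its limma adjusted p was under 0.05.

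The targeted gene was read by 4 probe sets, all lower in the Cre liver than in both control livers. Probe set 1421983_s_at was at 7.69 and 7.72 in the controls and 6.52 in the Cre liver, a 2.27-fold fall (-1.18 ± 0.14 SE, adjusted p = 0.0364 over 31526 probe sets). The brightest, 1427001_s_at, was at 11.91 and 11.96 against 11.38 (-0.55 ± 0.09 SE, adjusted p = 0.0644). Probe sets 1427000_at (-0.67 ± 0.24 SE, adjusted p = 0.21; -0.42 without control 2) and 1450447_at (-0.61 ± 0.21 SE, adjusted p = 0.193) did not pass. At gene level, where 1427001_s_at stood for Hnf4a, the adjusted p was 0.0401, and it ranged from 0.0103 to 0.184 over 9 other settings; that of 1421983_s_at ranged from 0.00215 to 0.0789 over 6. Probe positions relative to the floxed part were not used here, so a probe set outside the deleted part would check nothing.

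In the liver given Cre virus, 855 genes rose and 663 fell among 12735 genes fitted. Cyp2c54, a cytochrome P450, was 154-fold lower (-7.27 ± 0.19 SE), Haao, an enzyme of the kynurenine pathway, 111-fold lower (-6.80 ± 0.13 SE), and Otc, a urea cycle enzyme, 67.0-fold lower (-6.07 ± 0.15 SE). Dio1, which deiodinates thyroid hormone, fell from a control mean of 9.68 to 3.06, a level below the 3.77 used as the filter on dim genes, so the size of its fall and its place among the largest are uncertain. Among the largest rises were Pcp4l1 (5.15 ± 0.20 SE), the immediate early gene Egr1 (5.06 ± 0.46 SE), Serpina7, which encodes thyroxine-binding globulin (4.63 ± 0.42 SE), and Ccnd1, which encodes cyclin D1 (4.29 ± 0.22 SE). The other genes of the 10 largest falls were Cyp2a12, Cyp2d26, Mfsd2a, Glyat, Keg1 and Fam47e, between -6.14 and -5.74, with Fam47e also below the filter value in the Cre liver (2.53). Those of the 10 largest rises were Rad51b, Rcan2, Defb1, Acot3, Cyfip2 and Pdk4, between 5.14 and 3.90. In the Cre liver Mfsd2a (3.795) ended just above the filter value and Haao (4.42) near the median of all probe sets (4.155), so their sizes are uncertain too. The same holds for rises from low control means, such as Defb1 (4.05) and Cyfip2 (4.08).

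Some of these sizes depended on the probe set read. Rad51b rose by 5.14 on probe set 1421430_at, and its other probe set stayed at 3.02 and 3.01 in the controls and 3.01 in the Cre liver, so the mean of both gave 2.57. Averaging probe sets also gave 2.41 for Rcan2, 2.79 for Cyfip2 and 3.50 for Defb1, and -4.93 for Glyat and -5.39 for Otc. Without probe sets named as shared or mixed, Glyat was at -2.85 and Otc at -3.75.

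By size alone, 468 genes were at least 2-fold higher and 474 at least 2-fold lower than both controls, of which 449 and 450 also passed the test. The controls differed from each other by at least 2-fold in 82 genes, against 1244 and 1194 genes between the Cre array and each single control. The test assumed that Cre livers vary as the controls do, and differences between these mice, genotype included, cannot be separated from the difference between the viruses. Of the 12735 fitted genes, 3977 had an unadjusted p under 0.05 by limma's test. That count is not corrected for the number of genes tested and is not a count of changed genes.

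**Figure D1:**
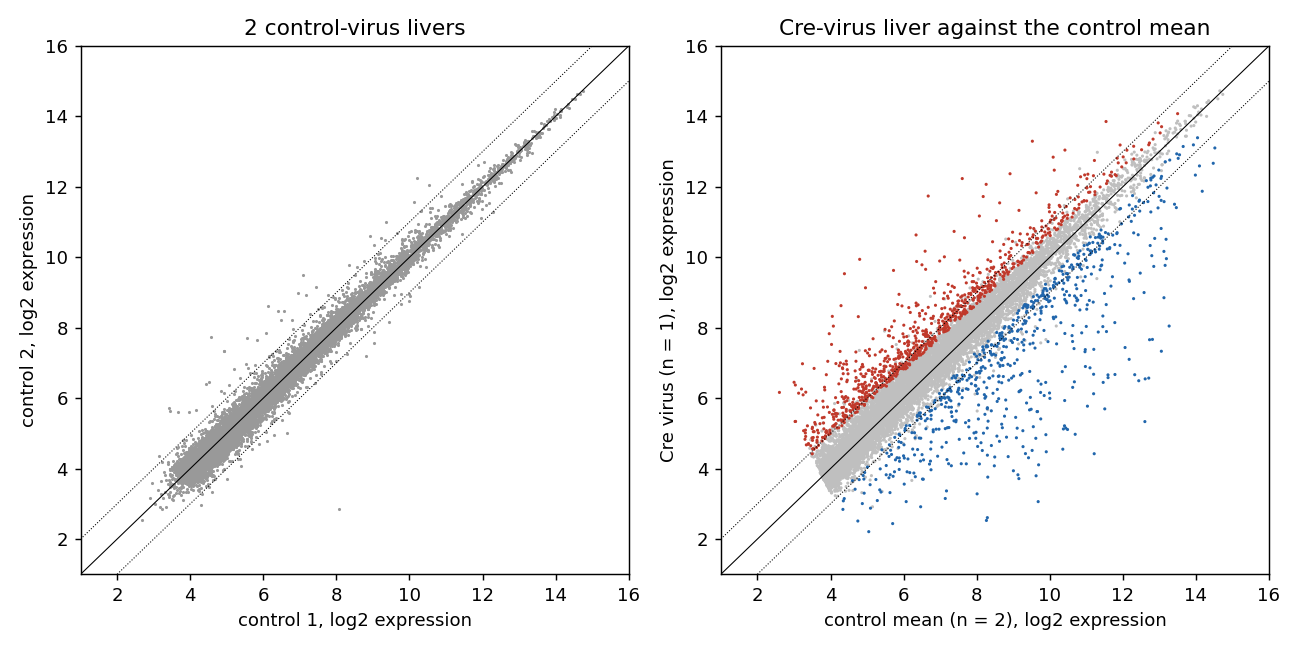
Log2 expression of each fitted gene in control liver 2 against control liver 1 (left) and in the Cre liver (n = 1) against the control mean (n = 2, right); each point is a gene, the solid line marks equal values and the dotted lines a 2-fold difference. Red points are the 855 genes that rose and blue points the 663 that fell by limma's test; 82 genes in the left panel lie on or beyond the dotted lines.

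**Figure D2:**
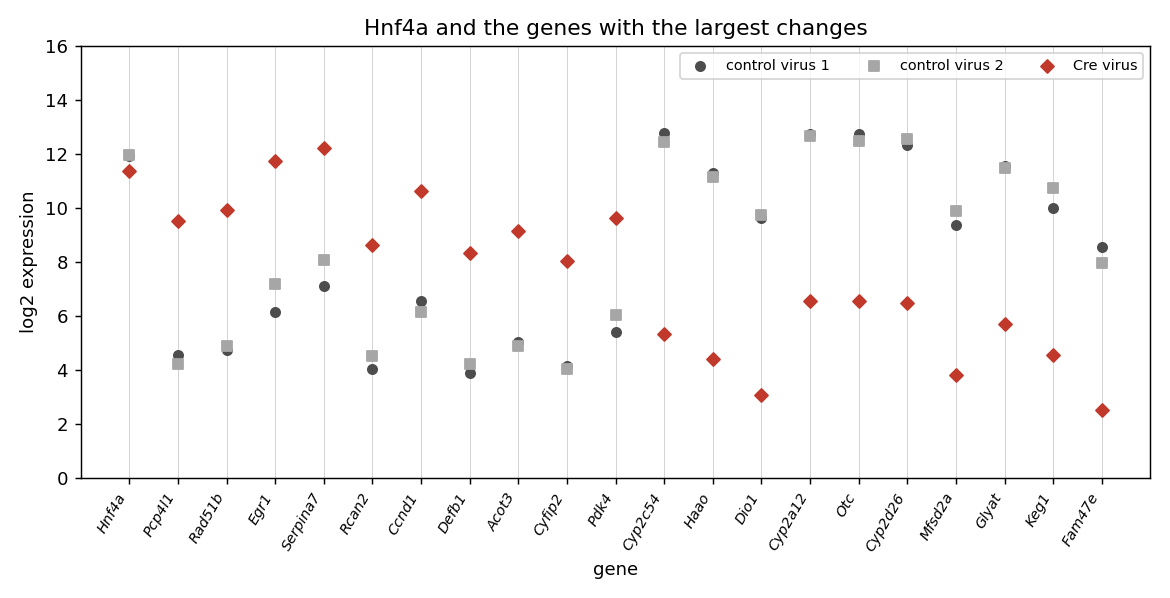
Log2 expression on each array for Hnf4a and the genes with the 10 largest rises and 10 largest falls; circles and squares are the control livers and diamonds the Cre liver, with no error bars because each point is 1 array. Hnf4a lay at 11.38 in the Cre liver against a control mean of 11.94, and Cyp2c54 fell by 7.27 on the log2 scale.

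Of 18 fitted genes for apolipoproteins and lipoprotein assembly, 12 fell and none rose (13 fell adjusted over the list alone), with Apoa4 at -5.11 ± 0.43 SE, Apom at -5.07 ± 0.17 SE, Apob at -2.96 ± 0.15 SE and Mttp, which loads lipid onto apolipoprotein B, at -2.65 ± 0.16 SE. Apoa1 (0.09) and Apoe (-0.29) did not pass. The list median was -1.31 (camera adjusted p = 1.88e-10; adjusted p = 0.65 with an estimated correlation). Of 13 complement genes, 10 fell (12 adjusted over the list alone), led by C8a (-5.66 ± 0.11 SE), C8g (-5.14 ± 0.10 SE) and Mbl2 (-3.59 ± 0.11 SE). Their median was -1.21 (adjusted p = 8.12e-12; adjusted p = 0.65 with an estimated correlation). In coagulation and fibrinolysis 11 of 21 genes fell (14 adjusted over the list alone), among them F13b (-5.26 ± 0.12 SE), Proz (-5.19 ± 0.13 SE) and F12 (-4.08 ± 0.12 SE), while the fibrinogen genes Fga (-0.15), Fgb (0.16; 0.05 without control 1 and 0.26 without control 2) and Fgg (-0.30) did not pass. That list's median was -0.51 (adjusted p = 1.17e-09; adjusted p = 0.65 with an estimated correlation). Proz was at -4.48 as the mean of its probe sets.

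Plasma carrier proteins and protease inhibitors went both ways. Of 16 genes, 4 rose and 3 fell (5 and 4 adjusted over the list alone). Serpina7 and Serpina6, which encodes corticosteroid-binding globulin (1.65 ± 0.16 SE), rose, and Igf1 fell (-0.91 ± 0.09 SE; -1.65 without shared or mixed probe sets). Alb, the albumin gene, was at -0.11 ± 0.07 SE and Ttr at -0.10, and neither passed. The median was 0.08 (-0.06 without control 1 and 0.12 without control 2) and the mean 0.35, whereas the test pointed down without passing (adjusted p = 0.923).

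Genes of bile acid synthesis, conjugation and transport changed in both directions. Baat (-5.11 ± 0.15 SE) and Slc27a5 (-5.07 ± 0.11 SE), which conjugate bile acids, fell, as did Cyp8b1, the sterol 12-alpha-hydroxylase (-3.60 ± 0.38 SE). Cyp39a1, an oxysterol hydroxylase, rose (2.73 ± 0.33 SE), and Cyp7a1, the rate-limiting enzyme, was at 1.31 ± 0.34 SE without passing. Of 13 synthesis and conjugation genes, 6 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.000925; adjusted p = 0.65 with an estimated correlation). Of 16 transporter genes, 4 fell and 3 rose (5 and 4 adjusted over the list alone). The uptake carriers Slco2b1 (-4.93 ± 0.13 SE), Slco1a1 (-3.65 ± 0.11 SE) and Slc10a1 (-2.81 ± 0.15 SE) fell, and the efflux pumps Abcc3 (1.26 ± 0.14 SE) and Abcc2 (0.61) rose. Slco1a4, of the same carrier family as Slco1a1, rose as well (1.30 ± 0.15 SE), so uptake carriers went both ways. Slco1b2 (-0.36), Abcb11 (0.30), Abcg5 (-1.04) and Abcg8 (-0.745) did not pass. The transporter list did not pass (median -0.26, adjusted p = 0.0509), and its adjusted p ranged from 0.00019 to 0.233 over 9 other settings. Without shared or mixed probe sets Baat was at -3.59 and Slco2b1 at -2.81.

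Nitrogen and glucose metabolism fell in part. Of 8 urea cycle genes 4 fell (4 fell and 1 rose adjusted over the list alone), namely Otc, Slc25a15 (-1.21 ± 0.11 SE), Ass1 (-0.80 ± 0.13 SE) and Asl (-0.70 ± 0.10 SE), while Cps1 (0.33) and Arg1 (0.23) did not pass over all genes. The list median was -0.51 (adjusted p = 0.00429; adjusted p = 0.65 with an estimated correlation). Of 21 genes of amino acid catabolism, 10 fell and 3 rose (10 and 4 adjusted over the list alone). The histidine-degrading enzymes Uroc1 (-3.02 ± 0.12 SE) and Hal (-1.88 ± 0.11 SE) fell, and Mat1a (0.85 ± 0.09 SE), Cbs (0.70 ± 0.10 SE) and Cth (0.68 ± 0.10 SE), enzymes of methionine and cysteine metabolism, rose. Their median was -0.20 (adjusted p = 0.000412; adjusted p = 0.65 with an estimated correlation). Gluconeogenesis and glucose handling had 8 of 11 genes lower (10 lower and 1 higher adjusted over the list alone), including Gys2, the liver glycogen synthase (-2.37 ± 0.13 SE), Pcx, pyruvate carboxylase (-1.94 ± 0.11 SE), and Pck1 (-0.73), with a median of -0.82 (adjusted p = 2.41e-07; adjusted p = 0.65 with an estimated correlation). The adjusted p of Ass1 and Asl reached 0.0592 and 0.0689 in other settings, from lowest values of 0.00897 and 0.00817.

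Of 16 xenobiotic cytochrome P450 genes, 11 fell and none rose over all genes (13 fell and 1 rose adjusted over the list alone), with Cyp2c54, Cyp2c50 (-5.72 ± 0.16 SE), Cyp2f2 (-5.22 ± 0.10 SE) and Cyp2c37 (-3.64 ± 0.28 SE) lowest while Cyp2e1 (0.06) and Cyp2b10 (0.89) did not pass over all genes. The median was -1.13 (adjusted p = 7.64e-11; adjusted p = 0.65 with an estimated correlation). Members of this family are close in sequence, so probe sets can read more than 1 of them. Conjugating enzymes split, with 6 of 21 lower and 5 higher (8 and 9 adjusted over the list alone). The sulfotransferases Sult1b1 (-5.69 ± 0.15 SE, to a level of 2.61, below the filter value) and Sult1a1 (-4.63 ± 0.13 SE) fell, and the glutathione transferases Gstm2 (2.91 ± 0.15 SE) and Gstm3 (2.75 ± 0.32 SE) rose. The median was 0.27 (0.02 without control 2) but the mean -0.42 and the test pointed down (adjusted p = 0.653).

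Of 18 fatty acid oxidation genes and targets of PPARalpha, a receptor that activates fat burning, 10 rose and 1 fell (13 and 2 adjusted over the list alone). Pdk4, which restrains pyruvate oxidation, was 14.9-fold higher (3.90 ± 0.30 SE), Acot1 was at 3.35 ± 0.50 SE, Cyp4a14 at 3.10 ± 0.44 SE and the peroxisomal enzyme Ehhadh at 2.63 ± 0.10 SE, while the fatty acid binding protein gene Fabp1 fell (-1.50 ± 0.13 SE). The list median was 0.94 (adjusted p = 0.000707; adjusted p = 0.683 with an estimated correlation), and the controls differed in it by 0.25. The adjusted p of Acot1 reached 0.0552 and that of Cyp4a14 0.0521 in other settings, from lowest values of 0.00235 and 0.00204. Fatty acid synthesis and lipid storage had 2 of 21 genes higher and 3 lower (6 and 4 adjusted over the list alone). Cd36, a fatty acid transporter, rose (2.43 ± 0.38 SE; adjusted p between 0.0037 and 0.0613 over 9 other settings), and Fitm1 (-2.65 ± 0.36 SE) and the desaturase gene Scd1 (-2.06 ± 0.10 SE) fell. Their median and mean were 0.07 and 0.06 (median 0.13 without control 1 and 0.01 without control 2), and the test pointed down without passing (adjusted p = 0.771).

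Of 14 cholesterol synthesis and uptake genes, 3 fell (7 adjusted over the list alone), Sc5d at -2.06 ± 0.23 SE (-1.40 as the mean of its probe sets), Nsdhl at -1.92 ± 0.33 SE and Insig1 at -1.86 ± 0.30 SE, with a list median of -1.28 (adjusted p = 0.000152; adjusted p = 0.683 with an estimated correlation). The control livers themselves differed by a median of 0.96 in this list, whose median was -1.71 without control 1 and -0.82 without control 2, and Idi1, which did not pass (-2.13 ± 0.70 SE), was at -2.95 without control 1 and -1.31 without control 2. The adjusted p of Nsdhl reached 0.071 and that of Insig1 0.0633 in other settings, from lowest values of 0.0037 and 0.00283. Among 17 hepatic transcription factors, 3 rose and 3 fell (3 and 5 adjusted over the list alone). Nr1i3, the xenobiotic receptor CAR, fell (-3.18 ± 0.14 SE), as did Cebpa (-1.26 ± 0.13 SE) and Cebpb (-1.04 ± 0.12 SE), and Foxa3 (1.10 ± 0.13 SE), Nr0b2 (1.05 ± 0.15 SE) and Foxa1 (0.95 ± 0.17 SE) rose. Ppara was at -1.58 ± 0.32 SE without passing (adjusted p = 0.054), and passed in some other settings (-1.62 after quantile normalization). The list did not pass (adjusted p = 0.335), and its median of -0.12 turned positive whichever control was left out (0.04 without control 1 and 0.05 without control 2). Of 13 epithelial junction genes, 7 fell (7 adjusted over the list alone), 5 of them claudins, with Cldn2 at -4.21 ± 0.19 SE, Cldn1 at -2.54 ± 0.13 SE and Gjb2 at -1.70 ± 0.15 SE. That median was -0.79 (adjusted p = 3.87e-05; adjusted p = 0.65 with an estimated correlation). As means of their probe sets Cldn2 was at -2.59 and Cldn1 at -0.83, and without shared or mixed probe sets Cldn1 was at -0.68 and did not pass (adjusted p = 0.246, against values from 8.06e-05 over 9 settings). Of the Cldn1 probe sets averaged, 1438850_at and 1438851_x_at lay below the filter value on every array (1.973 and 2.185 in the Cre liver). They shrink that mean without showing whether the transcript changed.

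Of 21 cell cycle genes, 11 rose and none fell (13 rose adjusted over the list alone). Ccnd1 was 19.6-fold higher, and the mitotic genes Birc5 (3.33 ± 0.23 SE), Mki67 (3.05 ± 0.18 SE), Ccnb2 (2.85 ± 0.19 SE), Ccna2 (2.68 ± 0.17 SE) and Cdk1 (2.07 ± 0.16 SE) rose. Mcm4, Mcm5 and Mcm6, also in this list, rose too. Pcna (-0.04, with -0.02 without control 1 and -0.06 without control 2), Mcm2 (-0.16) and Top2a (0.43) did not pass. The control means of Birc5 (3.04), Mki67 (3.21) and Ccnb2 (3.32) lay below the filter value, so the sizes of these rises are uncertain. Birc5, Mki67 and Ccnb2 passed the filter only through their Cre values, because its mean covered all arrays. Of 24 list members on the array 21 were fitted. Members dim in every liver were left out, so the filter favoured rises in this list. The list median was 0.88 (adjusted p = 8.12e-05; adjusted p = 0.65 with an estimated correlation), with an adjusted p of 1.69e-09 to 0.0575 over 9 other settings. Of 9 p53 targets, 3 rose (7 rose and 1 fell adjusted over the list alone), Eda2r (1.44 ± 0.18 SE, of uncertain size from a control mean of 3.64, below the filter value), Btg2 (0.97 ± 0.13 SE) and Ccng1 (0.71), and Cdkn1a was at 1.72 ± 0.42 SE without passing. Their median was 0.71 (adjusted p = 0.0412, from 0.00357 to 0.187 over 9 other settings; adjusted p = 0.65 with an estimated correlation). Of 9 fetal liver genes, 2 rose (2 adjusted over the list alone), Lpl (1.79 ± 0.15 SE) and Afp (1.56 ± 0.18 SE). Without shared or mixed probe sets Afp was at 0.05 and did not pass (adjusted p = 0.884, against values from 0.00445 over 7 settings), and the list did not pass (median 0.33, -0.04 without control 2; adjusted p = 0.391).

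Inflammatory and stress genes were mixed. Of 18 acute phase genes 5 rose and 6 fell (6 and 6 adjusted over the list alone), with Saa1 (-2.98 ± 0.17 SE) and Crp (-2.04 ± 0.10 SE) lower and Fgl1 (2.35 ± 0.13 SE), Orm3 (2.19 ± 0.21 SE) and Socs3 (1.84 ± 0.17 SE) higher (median -0.01, 0.15 without control 1 and -0.15 without control 2; adjusted p = 0.617). Of 13 interferon response genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), Usp18 (2.62 ± 0.24 SE) and Cxcl10 (1.87 ± 0.22 SE, of uncertain size from a control mean of 3.65, below the filter value) among the first (median 0.17, 0.06 without control 2; adjusted p = 0.57). Among 14 genes of endoplasmic reticulum stress, Herpud1 fell (-1.01 ± 0.14 SE; 1 adjusted over the list alone) and the list did not pass (median -0.11, -0.03 without control 1; adjusted p = 0.165). Of 10 genes of oxidative stress and metal binding, 4 rose and 1 fell (5 and 1 adjusted over the list alone). The metallothionein genes Mt2 (3.81 ± 0.34 SE) and Mt1 (3.77 ± 0.41 SE) and Osgin1 (3.55 ± 0.17 SE) led, and Nqo1 (-0.23) and Hmox1 (-0.28) did not pass. Mt1 was at 2.40 as the mean of its probe sets and at 1.03 without shared or mixed ones, where it did not pass (adjusted p = 0.0903, against values from 0.000572 over 9 settings). The list median was 0.43 (adjusted p = 0.0932, from 0.0216 to 0.23 over 9 other settings).

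Markers of other cell types differed in direction, with genes rising in the macrophage list and falling in the erythroid list. Of 13 macrophage and Kupffer cell genes 2 rose (3 adjusted over the list alone), Mpeg1 (1.95 ± 0.27 SE) and Marco (1.88 ± 0.16 SE; 0.77 as the mean of its probe sets, which differ in sign). Their median was 0.65 and passed the test (adjusted p = 0.0383, from 0.0057 to 0.0551 over 9 other settings; adjusted p = 0.683 with an estimated correlation), and the controls differed in it by 0.41 (median 0.32 without control 1 and 0.90 without control 2). Sox9, a marker of bile duct cells, rose (2.35 ± 0.43 SE; 1.29 as the mean of its probe sets; adjusted p between 0.0116 and 0.0799 over 8 other settings), the only one of 6 in its list (1 adjusted over the list alone; median 0.25, 0.14 without control 2; adjusted p = 0.992). Among 12 stellate cell and fibroblast genes Lum passed (0.76 ± 0.14 SE; 0 adjusted over the list alone; adjusted p between 0.0321 and 0.0809 over 9 other settings), with a list median of 0.32 (0.19 without control 1; adjusted p = 0.137). No gene passed, over all genes or adjusted over the list alone, among 11 endothelial (median 0.25, 0.14 without control 1; adjusted p = 0.37), 10 lymphocyte (median -0.07, 0.02 without control 2; adjusted p = 0.653) and 5 neutrophil genes (median -0.38, -0.21 without control 1; adjusted p = 0.185). Of 3 fitted erythroid genes, too few for a list test, Alas2 (-3.27 ± 0.19 SE) and Klf1 (-1.91 ± 0.16 SE) fell (2 adjusted over the list alone).

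Genes that respond to handling of tissue were led by Egr1. Of 12 immediate early and heat shock genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Jun at 1.16 ± 0.15 SE, Dusp1 at -1.21 ± 0.12 SE and Fos at 1.08 without passing (median 0.50, 0.20 without control 2; adjusted p = 0.342). Of 16 clock genes 1 rose and 3 fell (2 and 7 adjusted over the list alone). Per1 (-0.99), Hlf (-0.97) and Nr1d2 (-0.90) fell, and Dbp did not pass (-2.38 ± 0.70 SE; -1.57 without control 1 and -3.19 without control 2). The clock list had a median of -0.28 (-0.46 without control 2; adjusted p = 0.0852, from 0.0388 to 0.15 over 9 other settings). None of 10 housekeeping genes passed, over all genes or adjusted over the list alone, with Actb at -0.02 (0.06 without control 1 and -0.10 without control 2) and Tbp at 0.01 (-0.04 without control 1 and 0.06 without control 2); the median was -0.01 (0.02 without control 1), the mean 0.10 and the test pointed up (adjusted p = 0.992).

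Among genes with sex-biased expression in mouse liver, male-biased genes fell and female-biased genes rose where they passed the test. Of 11 male-biased genes 7 fell (9 adjusted over the list alone), with Hsd3b5 at -3.82 ± 0.13 SE, Slco1a1 at -3.65 ± 0.11 SE, Cyp2u1 at -3.10 ± 0.15 SE (-2.01 as the mean of its probe sets) and Ugt2b1 at -2.67 ± 0.10 SE. Their median was -1.63 (adjusted p = 5.81e-09; adjusted p = 0.65 with an estimated correlation), and 5 of the 11 were also in another list. Of 16 female-biased genes listed, 11 were on the array and 5 were fitted. The others on the array had means below the filter value, the Cre array included, so the filter favoured rises in this list. Among the 5 fitted genes 4 rose (4 adjusted over the list alone), Acot3 (4.17 ± 0.16 SE), Cyp17a1 (2.82 ± 0.15 SE), Cyp2b9 (1.48 ± 0.19 SE) and Fmo2 (1.08 ± 0.16 SE), and Cux2 was at -0.04. The median of the 5 was 1.48 (camera adjusted p = 0.00321, and 0.65 with an estimated correlation). Over 7 other settings the adjusted p of the list ranged from 0.00101 to 0.205, and the list did not pass without a filter (0.205). Fmo2 was at 0.33 without shared or mixed probe sets and did not pass (adjusted p = 0.289, against values from 0.0143 over 9 settings). The Y-linked Eif2s3y was at 7.70 and 7.75 in the controls and 8.07 in the Cre liver, and the X-inactivation transcript Xist at 3.36, 3.59 and 3.17. None of 3 fitted sex chromosome genes passed, over all genes or adjusted over the list alone, with a median of 0.35.

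**Figure D3:**
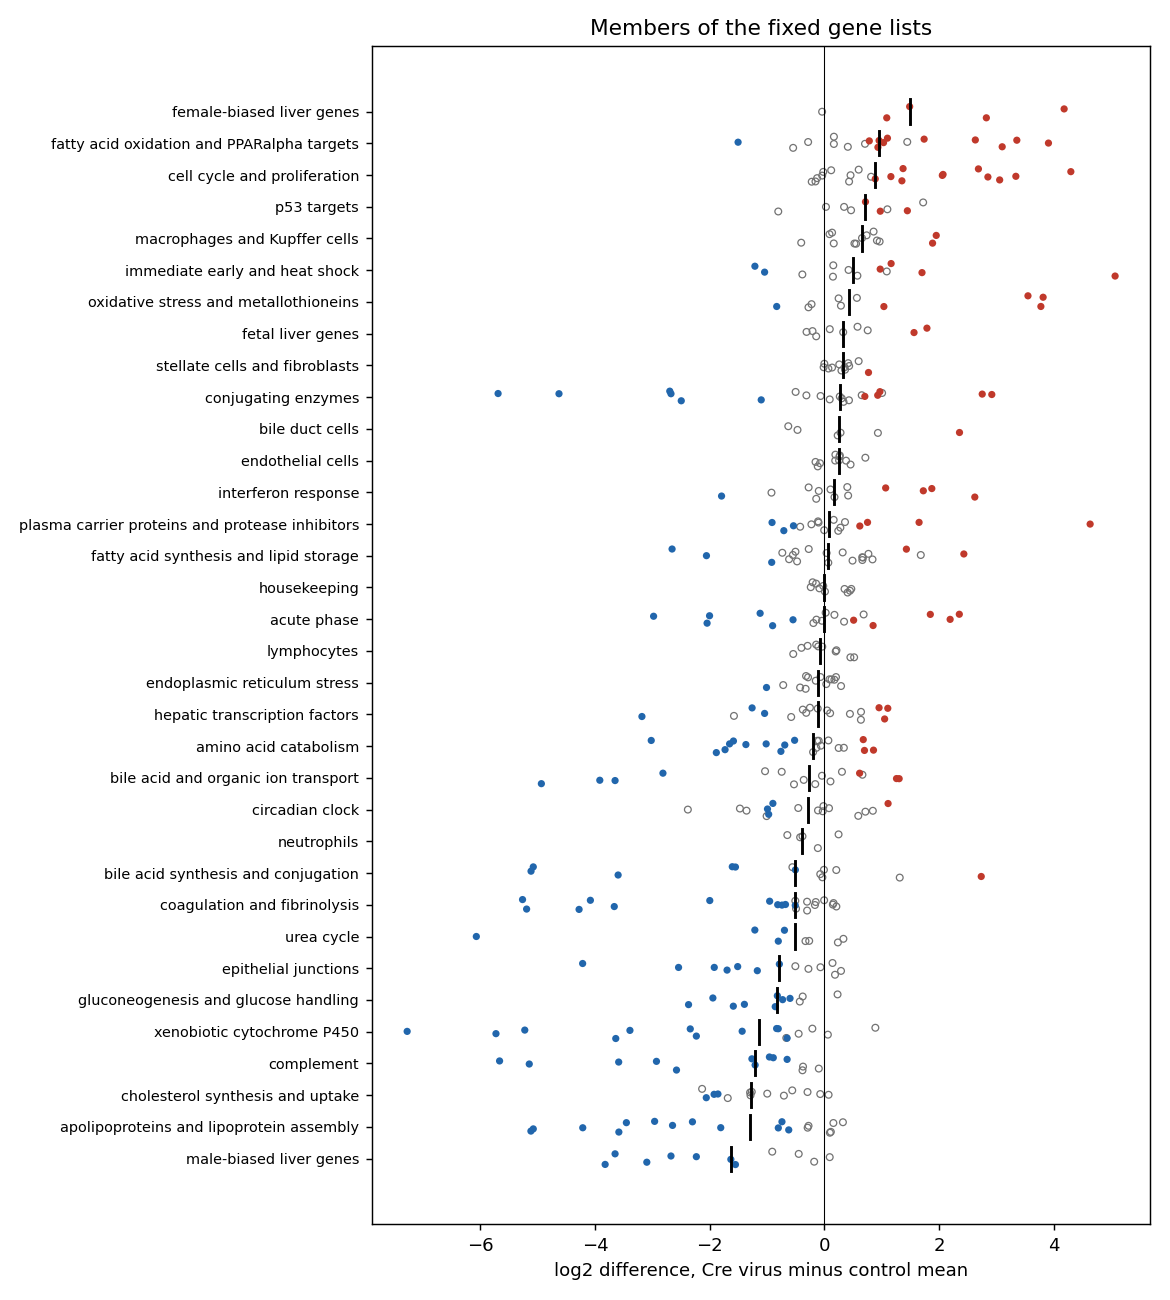
Log2 difference, Cre virus (n = 1) minus the control mean (n = 2), of each fitted member of the 34 tested gene lists, ordered by list median (black bar). Filled points passed limma's test (red higher, blue lower), open points did not, and list medians ran from -1.63 for male-biased genes to 1.48 for female-biased genes.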

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

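The tests of hepatocyte share through plasma protein genes, of escaped hepatocytes, of probe location and those of the sex-biased genes were chosen after the results were seen; the other tests were set before. The groups were too small to look for outlying samples.

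Outside the gene-level comparison, 67 probe sets with no listed gene and 26 that list several genes were at least 2-fold above both controls in the Cre liver, and 70 and 14 were at least 2-fold below. Between the controls 28 and 6 probe sets of these kinds were at least 2-fold apart, counted over all 3318 and 594 past the filter. Of the 64 array control probe sets 1 was at least 2-fold above both controls, AFFX-MURINE_b1_at, at 9.30 and 9.21 in the controls and 10.33 in the Cre liver. A control probe set for mouse pyruvate carboxylase, AFFX-PyruCarbMur/L09192_3_at, was at 10.35 and 10.36 against 8.49, beside the fall of Pcx by 1.94.

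The genes at least 2-fold from both controls, 468 higher and 474 lower, come from a single Cre mouse, and a mouse of another sex is argued against by sex chromosome genes, whose median absolute difference from the controls was 0.328 on the log2 scale, with the controls at most 0.309 apart. Ordinary differences between mice are argued against by the controls, which differed 2-fold in 6.87% as many genes as the Cre array did from a single control, although 1 pair of mice measures that spread. Markers of other cell types, over lists of at least 5 fitted genes, left a changed share of cells undecided (the interval of the highest list median overlapped that of the lowest, with a gap of -0.083, -0.784 without control 1 and 0.141 without control 2); 3 erythroid genes, too few for that test, lay between -3.27 and -0.48, all below the interval of the macrophage list (0.16 to 0.91). In a test added after that, a smaller share of hepatocytes would lower plasma carrier genes alike. Their median was 0.08 (bootstrap interval over genes -0.23 to 0.39), or -0.06 without control 1 and 0.12 without control 2. The lower bound lay 1.68 above the median of the genes at least 2-fold lower (-1.91), a gap of 1.73 without control 1 and 1.68 without control 2. Those lower genes were picked for their fall, so part of this gap was fixed in advance. What the values show is narrower: the plasma carrier genes as a set did not fall in this 1 Cre mouse. For the higher genes a changed share of single cell types stays open, as do the response to the Cre virus itself, a difference in genotype before injection and a trait of this mouse, which were not tested, beside loss of HNF4alpha as the design's explanation.

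Hnf4a probe sets were lower by less than many other genes, at 44.1% to 68.1% of the control mean, and 1 of the 4 passed the test. A remainder of hepatocytes that escaped recombination and kept control levels would stop other transcripts from falling further, whereas 275 genes lay below the largest Hnf4a fall by more than 3 SE. These values speak only against escaped hepatocytes as the source of all the remaining Hnf4a signal. A smaller share of escaped hepatocytes stays open. Probe sets that read transcript left in place by recombination may account for the remaining signal; the probe sets differed in their fall by 0.628 on the log2 scale, and without their positions this cannot be told apart from a partial loss of the transcript. Signal from Hnf4a transcript in other cells was not tested.

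Of 11 male-biased genes 7 fell and of 5 fitted female-biased genes, from 11 on the array, 4 rose (adjusted p = 0.65 with an estimated correlation for each list) in a liver whose sex chromosome genes differed from the controls by a median of 0.328, which argues against a mouse of another sex. A general fall of hepatocyte genes stays open: of random draws of 11 from 252 hepatocyte function genes outside the list (median -0.40), 1.34% had a median at or below that of the male-biased list (-1.63), a share of 2.77% without control 1 and 0.69% without control 2. These draws were not matched on expression, and members regulated together make that share too small. Loss of HNF4alpha, the virus, genotype before injection and a trait of this mouse all stay open, since no test here separates them.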

How the results depend on the processing

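All alternatives here were planned. The count of genes past the threshold, 1518, was 955 without a filter (446 higher), 923 without shared or mixed probe sets (471 higher), 2783 at an adjusted p under 0.10 (1780 higher, 1003 lower), and 449 when tested against a fold of 1.5 (148 higher, 301 lower); after quantile normalization 1000 fell. The size rule gave 853 higher and 801 lower with every probe set alone (194 between the controls), 85 and 202 at 4-fold (12), and 1346 and 855 at 1.5-fold (505), as more probe sets or a looser size must. Leaving out a control leaves 1 array against 1 and no test. By size 613 to 695 genes were then higher and 549 to 581 lower, and of 310 values of named genes 1 changed sign. Named genes were chosen for large changes or for lying outside both controls, so few of them could change sign. Some list members outside that choice did, such as Sqle (-1.73 without control 1 and 0.31 without control 2). Of 34 list medians 19 moved by more than the spread between the controls without control 1 and 20 without control 2, by at most 0.43 and 0.46; 4 and 3 changed sign, 0 of them in a list that passed. Over all settings 136 list medians moved by more than that spread and 164 did not. For Hnf4a, 1421983_s_at kept its value (-1.18) without passing when eBayes had no trend (adjusted p = 0.0578) or no filter was set (0.0789), in a range of 0.00215 to 0.0789; 1427000_at passed after quantile normalization (-0.70; range 0.0495 to 0.311); 1427001_s_at passed with robust moderation and above the 50th percentile (-0.55), after centring (-0.54) and after quantile normalization (-0.59; range 0.00911 to 0.16). With an estimated correlation all 16 list calls were lost, at an adjusted p of 0.65, or 0.683 for fatty acid oxidation, cholesterol and macrophage genes; that test has 1 degree of freedom. Of the other list results, bile acid and ion transport passed above the 50th percentile (0.0256), after centring (0.0343) and per probe set (0.00019); the clock list above the 50th percentile (0.0388) and without shared or mixed probe sets (0.0471); oxidative stress without a filter (0.0378) and after quantile normalization (0.0216). Calls ended for cell cycle above the 50th percentile (0.0575), female-biased genes without a filter (0.205), macrophages per probe set (0.0551), and p53 targets above the 50th percentile (0.187), with averaged probe sets (0.0774) and without shared or mixed ones (0.117); ranges over the settings stand beside each list above. Polr2a, not called, changed sign to -0.042 with averaged probe sets. Of named gene values with a test, 50 lost and 22 gained a call. Except for the effects of construction named here, the cause was not tested. Robust moderation was not run for the list test, which has no such option. Signal near background limits the dimmest genes, and no detection calls were used. No paired analysis was possible because the Cre group has 1 mouse.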

Other observations

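Families of related genes were grouped by symbol stem after the data were seen, and many of their members are also in the fixed lists. The 223 families with at least 8 fitted genes were tested in each direction by Fisher's exact test (446 tests). At an adjusted p under 0.05, 5 passed for an excess of falling genes and 1 for an excess of rising genes. Among 9 retinol dehydrogenase genes 6 fell and none rose (exact adjusted p = 0.000319), 0 of the 6 in a fixed list, with Rdh9 at -3.81 ± 0.14 SE, Rdh16 at -3.75 ± 0.20 SE and Rdh5 at -2.69 ± 0.15 SE. Of 14 hydroxysteroid dehydrogenase genes 6 fell and 1, Hsd17b11, rose (exact adjusted p = 0.00455); Hsd3b2 was at -4.34 ± 0.16 SE, Hsd3b3 at -3.93 ± 0.16 SE and Hsd17b2 at -2.32 ± 0.18 SE, and 2 of the 6 are in a fixed list. Of 10 UDP-glucuronosyltransferase and UDP-glycosyltransferase genes 5 fell and 2, Ugt2b34 and Ugt2b35, rose (exact adjusted p = 0.0068), with Ugt3a2 at -4.52 ± 0.14 SE and Ugt2b38 at -4.41 ± 0.15 SE and 2 of the 5 in a fixed list. Acyl-CoA thioesterase genes had 5 of 11 higher and 1, Acot12, lower (exact adjusted p = 0.0329), with Acot2 at 2.90 ± 0.22 SE and Acot9 at 2.08 ± 0.18 SE; 2 of the 5, Acot1 and Acot3, are in a fixed list. The other families mostly restate the lists: of 28 genes of the cytochrome P450 family 2, 16 fell and 2 rose (Cyp2b9 and Cyp2j6; exact adjusted p = 1.85e-11), with 10 of the 16 in a fixed list, and of 9 claudin genes 5 fell (exact adjusted p = 0.00455), all 5 in a fixed list. Genes of a family can share sequence, so they are not independent, and family medians kept their direction after median centring and after quantile normalization.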
